A study of Mus musculus with 14 samples.

How the data were processed

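The series holds 14 mouse samples, of which 9 are ChIP-seq libraries and 5 are inputs. Brg1 was profiled in fetal liver cells in 5 libraries. Per the labels, these were EBF1-deficient c-kit-positive progenitors from embryos of day 16 to 18, transduced with an empty vector or with EBF1 wt, dC, dPLD (residues 480 to 520 deleted) or F-GATA3, and kept for 14 to 20 days on OP9 stroma. Brg1 was also profiled in 2 libraries and EBF1 in another 2 from A-MuLV pro-B cells with EBF1 replaced by wt or dC. Crosslinking, per the labels' protocols, used 2% formaldehyde with EGS in fetal liver cells, 1% with EGS for A-MuLV Brg1, and 1% formaldehyde alone for A-MuLV EBF1. The labels describe a single fetal liver input, from EBF1 wt pro-B cells, and 4 A-MuLV inputs. Each group had 1 library.

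The submitters' processing notes name Bowtie2 2.3.3.1, SAMtools 1.9, deepTools 3.3.1 and MACS2 2.1.2 and the build GRCm38. The 9 peak lists were used, and signal tracks and reads were not analysed here. Each list gives base positions of the peak and its summit as deposited by the authors. The authors' fold enrichment is the ratio of the ChIP pileup at the summit to the local background. The authors' −log10 p and −log10 q values are those of MACS2 at the summit, and the deposited score is 10 times the −log10 q, cut to a whole number. The meaning of these columns comes from the peak format and was checked on the values. The threshold, the handling of duplicate reads and the input set against each library are not given in the sources used here. The values show a floor near a −log10 q of 10 in the fetal liver and EBF1 lists, and lower values down to 1.37 and 1.33 in the A-MuLV Brg1 wt and dC lists.

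Peaks on chromosomes 1 to 19, X and Y were used, and peaks on unplaced scaffolds were left out. A peak counted as called in another list when the intervals shared at least 1 bp. Gained peaks are fetal liver wt peaks that overlap no empty-vector peak, and the remaining wt peaks are called shared. EBF1 sites called with both forms or with wt alone are intervals of the EBF1 wt list, and those called with dC alone are intervals of the dC list. Shares carry exact Clopper-Pearson 95% intervals from scipy. For a pair of libraries, the sites called in 1 and not the other were counted, and their split was given with the same interval. Overlap by chance came from 100 random circular shifts of the sites along their chromosomes. No test was made across conditions, because each condition had 1 library, and there was no replicate to check against.

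Gene positions came from a RefSeq table for GRCm38 patch 6, which gives start and end of 21887 protein-coding genes and neither strand nor exons. The 9 gene lists, with 131 members, were fixed before the data were examined. These cover B-lineage, T-lineage, innate lymphoid and NK, myeloid, erythroid and megakaryocyte, progenitor, stromal, BAF and PBAF subunit, and ubiquitously expressed genes. A member counted when a peak of the class lay in its body extended by 10 kb. Percentiles place that count among 10000 random lists of protein-coding genes of the same size, matched on gene length in 20 bins. They describe these libraries and are not p-values, and 135 were computed over 15 classes of sites.

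The genes named follow a rule set before the data were examined. They are the 2 to 4 list members with the highest fold of a peak of the class, the 10 highest peaks of each main class, taken 1 per gene, and Ebf1, Gata3 and Smarca4 in every list. Peaks were named by the nearest protein-coding gene interval, ties going to the shorter gene, in place of the nearest transcription start, since the table holds no strand. Igk, Igh and the counts within Ikzf3 and Pax5 were added after their values had been seen. For Igk and Igh, peaks overlapping the locus were counted and the ratio to the wt count was compared with that of other windows of the same length along the genome.

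Alternatives were a −log10 q of at least 5, lists held to equal numbers of peaks, an overlap of 50% of the shorter peak, summits no more than 200 bp apart, gained peaks above the median fold of the shared peaks, and gene bodies extended by 50 kb. A −log10 q of at least 20 was added after the data had been seen, because the minimum of 5 removed no fetal liver or EBF1 peak. Sequence motifs and windows around transcription starts were not analysed, since neither sequence nor strand was used here.

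The lists held 17687 (empty vector), 29354 (wt), 30301 (dC), 27550 (dPLD) and 25072 (F-GATA3) fetal liver Brg1 peaks, 24493 (wt) and 24420 (dC) A-MuLV Brg1 peaks, and 6155 (wt) and 11147 (dC) EBF1 peaks. Their median widths were 978, 1103, 1248, 1325, 1139, 381, 348, 363 and 386 bp in that order. Sequencing depth is unknown, so a site without a peak is not shown to lack the protein. The background pileup was solved from fold and −log10 p at 2000 peaks per list (1993 of them for EBF1 wt). It was 3.89 (empty vector), 4.01 (wt), 4.14 (dC), 4.17 (dPLD) and 4.01 (F-GATA3) in fetal liver, 1.65 (wt) and 1.9 (dC) for A-MuLV Brg1, and 2.83 (wt) and 2.65 (dC) for EBF1. Solved ChIP pileups were whole numbers at 1.4% (wt) to 4.2% (dPLD) of the fetal liver peaks and at 100% in each A-MuLV list. The fetal liver ChIP pileups thus appear rescaled. Their near-equal backgrounds do not show equal depth and cannot be set against those of A-MuLV cells.

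The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlap counts were checked with bedtools 2.31.1 and were the same for 72 of 72 ordered pairs of lists. The steps were tested on simulated data: planted shares were found with a largest gap of 0 points, and 96.2% of 600 background pileups were recovered. The exact interval covered the true share in 93.6% or more of the runs of each setting. A simulated gene list with nothing planted had a median percentile of 54.8, and one with planted sites 100.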

Results

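The series asks how the C-terminal domain of EBF1 bears on where Brg1 sits on chromatin. EBF1 is a transcription factor of early B cells, and Brg1, encoded by Smarca4, is an ATPase of the BAF chromatin remodelling complexes. All values come from lists of ChIP-seq peaks (GRCm38), with 1 library per group, so nothing was tested across conditions and no spread between replicates could be measured. Exact Clopper-Pearson 95% intervals stand in parentheses after shares of peaks. They cover counting error only and compare these libraries, not conditions. Fold enrichment is the authors' value per peak and serves here to describe and rank peaks within 1 list.

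Brg1 peaks seen with wild-type (wt) EBF1 and not with the empty vector lay near most genes of the B-cell programme. In EBF1-deficient fetal liver progenitors, such gained peaks lay within 10 kb of 25 of 26 B-lineage genes. The strongest were near Pou2af1 (fold 31.3), which encodes a B-cell coactivator, Pax5 (24.8), which encodes a B-lineage commitment factor, Cd79b (22.3), which encodes a chain of the B-cell receptor, and Cd22 (20.7), which encodes an inhibitory receptor of B cells. Random lists of protein-coding genes matched on length had a median of 13 members with a gained peak (2.5th to 97.5th percentile 8 to 18), and the B-lineage list stood at percentile 100 of the 10000 lists. Peaks shared with the empty vector also lay near 18 of the 26 (random median 10, percentile 99.91). Their wt folds were as high, with Bank1 (31.4), Bst1 (27.9) and Igll1 and Vpreb1 (27.6) highest. At those genes the highest gained peaks had folds of 14.1, 8.64 and 6.19. Strong Brg1 peaks near B-lineage genes were thus not confined to gained peaks. Summed over the genes, there were 132 wt and 50 empty-vector peaks, a peak near 2 members counting at each. Bach2 alone had 16 of the 50. The Pax5 gene held 10 Brg1 peaks with wt EBF1 and 0 with the empty vector, and the Ebf1 gene held 12 against 2. The highest gained peaks of the genome were nearest Iqsec1 (33.2; chromosome 6, 90763664 to 90765871), 9830107B12Rik (31.6), Rnf180 (31.5), Pou2af1 (31.3; chromosome 9, 51210555 to 51216383), Man1c1 (31.2), Rpia (30.8), Zbtb18 (30.2), Klhl24 (29.2), 1700056E22Rik (28.6) and Erfl (28.5).

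Most other gene groups stood closer to the random lists within 10 kb, though not all within 50 kb. Gained peaks lay near 9 of 16 T-lineage genes, among them Il2ra (8.49) and Tcf7 (8.37), against a random median of 9 (percentile 55.6). They lay near 5 of 12 innate lymphoid and NK genes, led by Klrb1c (8.55) and Rora (8.49; percentile 27.3), and near 7 of 12 progenitor genes, led by Erg (25.1) and Lmo2 (11.1; percentile 55.0). Of 14 myeloid genes 8 had a gained peak, with Fcgr3 (15.8) and Itgam (15.5) highest (percentile 86.1; 13 with a 50 kb window, percentile 99.42), and of 10 erythroid and megakaryocyte genes 6 had, with Pf4 (17.3) and Gp9 (14.0) highest (percentile 92.0; 10 with a 50 kb window, percentile 99.96). Genes of the BAF and PBAF complexes had 14 of 16 members with a gained peak, Smarca4 (17.2) and Smarce1 (14.6) foremost (percentile 99.4). Ubiquitously expressed genes had 11 of 14, among them Rpl13a (8.43) and Polr2a (8.19; percentile 98.7). Stromal genes, kept as a check because the cells grew on OP9 stroma, had 1 of 11, Col1a1 (6.19; percentile 0.06), and 3 with a 50 kb window.

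The wt list held 29354 Brg1 peaks and the empty-vector list 17687. Of the wt peaks, 18765 had no overlapping empty-vector peak (63.9%, 63.4-64.5%), and 10589 were shared. Gene bodies of the table used here held 63.6% of the gained and 71.0% of the shared peaks, and an EBF1 peak of A-MuLV cells overlapped 22.9% of the gained and 21.4% of the shared peaks. In the opposite direction, 6840 empty-vector peaks overlapped no wt peak. The gained count depended on list length: with every list held to its 17687 strongest peaks it was 9434. The labels place the empty-vector cells before the pro-B stage and the wt cells at it, so EBF1 and stage changed together.

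Most B-cell genes that gained Brg1 with wt EBF1 also had it with each altered EBF1. The compared versions were dC, which lacks the C-terminal domain, dPLD, which lacks residues 480 to 520, and F-GATA3, which carries the TA1 domain of GATA3 in place of the C-terminal domain. Gained peaks called with all 3 versions lay near 23 of 26 B-lineage genes (random median 10), Pou2af1, Pax5, Cd79b and Cd22 again being the strongest. All 10 of the highest gained peaks, from Iqsec1 to Erfl, were called with all 3. Gained peaks called with none of the 3 lay near 8 B-lineage genes (random median 2, percentile 99.98), at lower folds: Pax5 (6.77), Bach2 (6.73), Bst1 (6.55) and Vpreb2 (5.83).

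By share, dC kept 76.3% of the gained peaks (75.7-76.9%), dPLD 77.2% (76.6-77.8%) and F-GATA3 70.0% (69.4-70.7%). All 3 versions kept 10758 peaks (57.3%), and 1932 (10.3%) were called with none. The versions kept 96.6%, 94.9% and 89.5% of the peaks shared with the empty vector, and 94.0%, 90.5% and 80.8% of those after weighting to the folds of the gained peaks. Among 10 bins of wt fold, the highest, with folds of 13.0 or more, had 94.6% of its gained peaks kept by dC, 99.1% by dPLD and 99.7% by F-GATA3. The lowest bin had 67.2%, 64.0% and 49.4%. When the gained peaks were shifted at random along their chromosomes, the mean overlap with the 3 lists was 2.55% to 3.26%, and the highest of any shift was 3.84%. F-GATA3 had the shortest of the 4 lists with an EBF1 version, and with lists of equal length it no longer kept the fewest (dC 68.4%, dPLD 75.6%, F-GATA3 75.9%). Nor did it among gained peaks above the median fold of the shared peaks (89.3%, 95.4% and 95.7%).

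**Figure D1:**
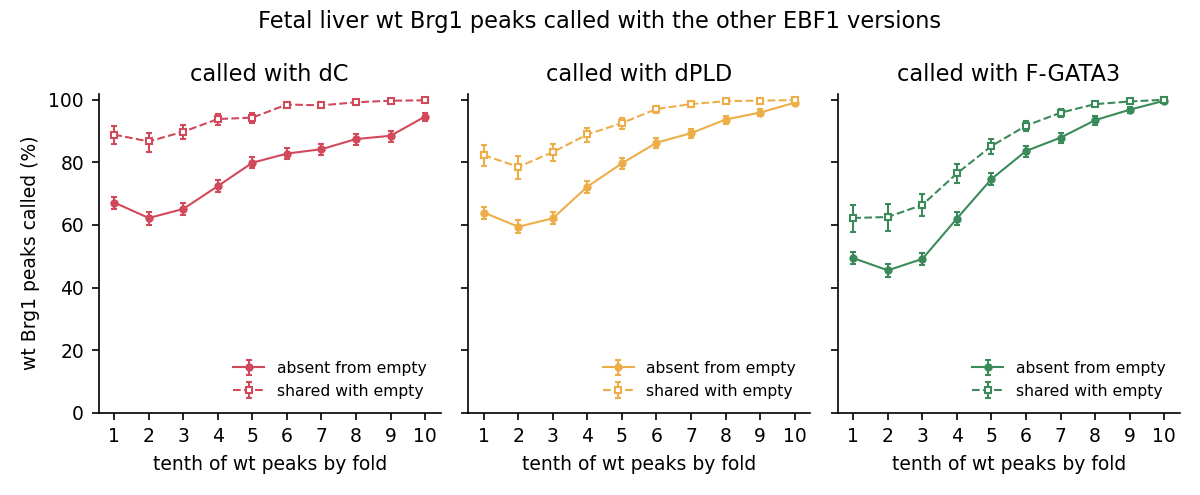
Share of fetal liver wt Brg1 peaks (percent, vertical axis) also called with dC, dPLD and F-GATA3, in 10 bins of the authors' wt fold (horizontal axis), for peaks absent from the empty-vector list and peaks shared with it, bars being exact 95% intervals. In the highest bin 94.6% (dC), 99.1% (dPLD) and 99.7% (F-GATA3) of the gained peaks were called, and in the lowest bin 67.2%, 64.0% and 49.4%.

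The versions parted at particular sites. Gained peaks called with F-GATA3 and with neither dC nor dPLD numbered 1108 (5.91% of the gained peaks), and those with high folds lay nearest Auts2 (17.5), Cntnap5c (16.5), Wwc1 (16.4), Urb1 (16.0), Sdk2, Ostf1, Steap3, Gria3 and Podxl. Ebf1 (10.5) and Pou2af1 (5.62) were the only B-lineage genes with such a peak within 10 kb (percentile 78.8), and 5 had one within 50 kb. Of these peaks 35.7% lay at an EBF1 site of A-MuLV cells, and 11.6% at a site called with EBF1 wt and not with EBF1 dC. The opposite set, called with dC and dPLD but not with F-GATA3, held 2319 peaks (12.4%), of which 13 (0.561%) lay at such a wt-only EBF1 site.

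Among the altered versions, peaks absent from the wt list were most numerous with dC, which had the longest list. There were 6288 in dC, 3622 in dPLD and 2346 in F-GATA3, and the empty-vector list had 6840. The highest in dC were nearest Hs6st1 (17.3), Chl1 (16.6), Syndig1 (16.2), Slc44a5, Ackr3, Adamts14, Ankrd55, Tgm2, Rab11fip5 and Car12. Each of these was also called with dPLD. Those nearest Slc44a5 (9.3), Ackr3 (10.6), Adamts14 (12.8), Tgm2 (12.5) and Rab11fip5 (7.09) were also called with the empty vector, at the folds given. Those nearest Slc44a5, Ackr3, Adamts14, Ankrd55 and Car12 were also called with F-GATA3. In dPLD the highest was nearest Wnt5b (14.2), and in F-GATA3 they were nearest Ryr2 (18.3), Dnaja4 (17.1), Hspg2 (15.3) and Hlx (14.0). Peaks of dC absent from wt lay near 4 of 10 erythroid and megakaryocyte genes, among them Itga2b (7.46; percentile 98.3), and those of dPLD also near 4, among them Hbb-bt (6.76) and Itga2b (6.08; percentile 99.5). Ubiquitously expressed genes stood as high, with 7 of 14 near the dC peaks, led by Rplp0 (7.07; percentile 99.65), and 6 near the dPLD peaks, led by Polr2a (6.53; percentile 99.78).

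At sites bound by EBF1, the fetal liver libraries ranked differently. EBF1 peaks were measured in A-MuLV cells, pro-B cells transformed by the Abelson virus whose EBF1 was replaced by wt or dC, and not in the fetal liver cells. Sites called with both EBF1 forms (n = 4719) lay near 19 of 26 B-lineage genes, with Igll1 and Vpreb1 (36.5), Vpreb2 (32.4) and Pax5 (31.4) highest. Igll1 and the Vpreb genes encode the surrogate light chain, and Igll1 and Vpreb1 share their highest peak. Brg1 peaks covered 76.4% of these sites with wt (75.1-77.6%), 70.9% with F-GATA3 (69.6-72.2%), 70.2% with dPLD (68.9-71.6%), 63.7% with dC (62.3-65.1%) and 20.8% with the empty vector (19.7-22.0%). The mean overlap over 100 random shifts of the sites was 0.802% to 2.52% across the Brg1 lists, for sites called with both EBF1 forms or with wt alone, and the highest of any shift was 3.69%.

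Counted site by site, 683 of the sites called with both EBF1 forms had Brg1 with wt and not dC, and 87 the reverse. Brg1 was called with F-GATA3 and not dC at 583 and the reverse at 243, and with dPLD and not dC at 379 and the reverse at 71. F-GATA3 and dPLD differed little, with 330 sites against 298 (52.5%, 48.6-56.5%). The contrast was wider at the 1436 sites called with EBF1 wt alone, which were selected for lacking an EBF1 dC peak. There Brg1 was called at 36.4% with F-GATA3 (33.9-39.0%), 35.9% with wt (33.4-38.5%), 23.0% with dPLD (20.8-25.2%), 15.5% with dC (13.6-17.4%) and 4.25% with the empty vector (3.27-5.42%). F-GATA3 without dC accounted for 336 of these sites and the reverse for 35. At the 6454 sites called with EBF1 dC alone, wt, dC and dPLD reached 45.3%, 45.5% and 45.3%, and F-GATA3 39.4%. The labels place wt and F-GATA3 cells at the pro-B stage and dC and dPLD cells partly blocked before it.

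**Figure D2:**
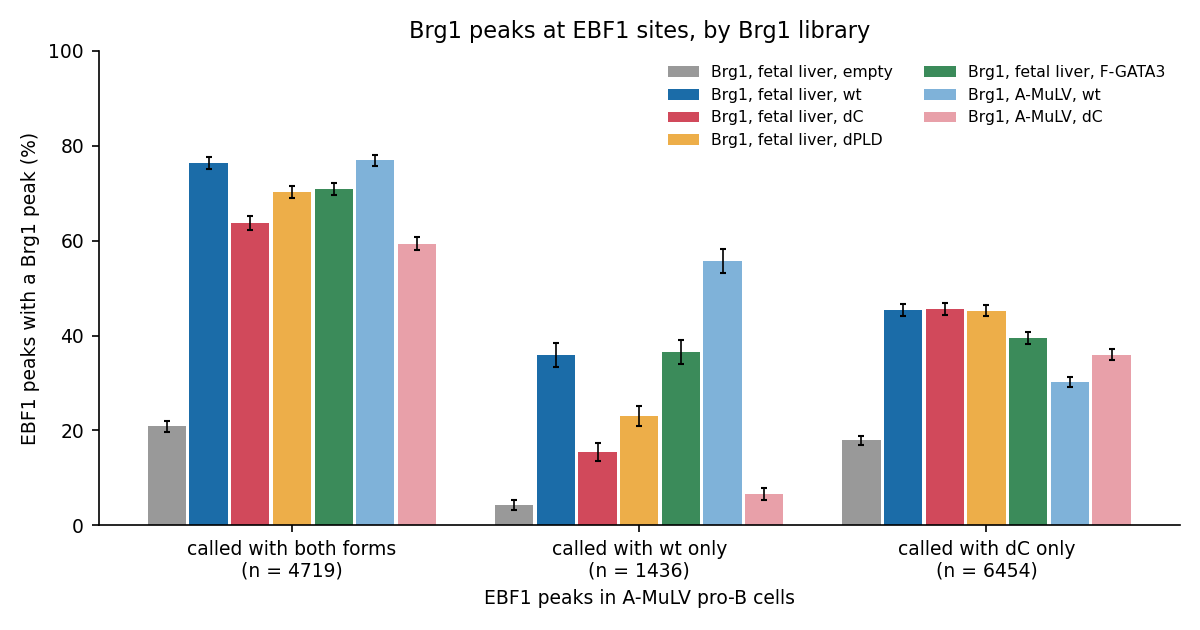
Share of A-MuLV EBF1 peaks that overlap a Brg1 peak (percent, vertical axis), for sites called with both EBF1 forms, wt alone or dC alone (horizontal axis), 1 bar per Brg1 library with exact 95% intervals. At wt-only sites the A-MuLV bars stand at 55.7% (wt) and 6.55% (dC), and the fetal liver bars at 35.9% (wt), 36.4% (F-GATA3), 23.0% (dPLD), 15.5% (dC) and 4.25% (empty vector).

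The same question could be put within A-MuLV cells, where Brg1 and EBF1 were measured in the same kind of cell. Among the strongest Brg1 peaks found with EBF1 wt and absent with dC were those nearest Clint1 (34.0; chromosome 11, 45874810 to 45876138), Megf6 (32.4), Tafa2 (29.5), Dab2ip (28.7), Tm2d1 (28.7), Ankrd12 (27.0), Pmf1 (26.1), Pan2 (26.1) and Epas1 (26.1). Each of these overlapped an EBF1 wt peak, and all but the one nearest Clint1 also overlapped an EBF1 dC peak, with EBF1 dC folds from 5.45 (Pan2) to 21.9 (Tm2d1). Wt-only Brg1 peaks lay near 22 of 26 B-lineage genes (random median 7, 3 to 12, percentile 100), led by Ikzf3 (15.1), which encodes the lymphoid factor Aiolos, Cd79b (7.41), Irf4 (6.77) and Pax5 (6.61). They also lay near 9 of 14 ubiquitously expressed genes, led by Eef1a1 (7.56; percentile 99.82), and 9 of 16 BAF and PBAF genes, led by Pbrm1 (9.68; percentile 98.52). Peaks called only with dC were highest nearest Naa11 (18.3), Cacna1b (17.6), Cbfa2t3 (17.5), B3gnt2 (16.2) and Ccl6 (15.9), with Erg (14.3) also among the 10 highest, and lay near 17 B-lineage genes, led by Bach2 (10.5), Bank1 (8.31), Rag1 (6.38) and Dntt (5.92; percentile 99.99), and 9 BAF and PBAF genes (percentile 98.35).

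Of 24493 A-MuLV Brg1 wt peaks, 62.4% (61.8-63.1%) were called with dC, and of 24420 dC peaks 65.6% (65.0-66.2%) were called with wt. Where both EBF1 forms were called, 72.0% of the wt Brg1 peaks were called with dC. At wt-only EBF1 sites the share was 12.6% (10.4-15.1%, n = 802), at dC-only sites 83.4% and away from EBF1 60.5%. Counted from the EBF1 sites, Brg1 covered 76.9% of those called with both forms in wt cells (75.7-78.1%) and 59.4% in dC cells (57.9-60.8%). At wt-only sites it covered 55.7% (53.1-58.3%) and 6.55% (5.32-7.95%), with 714 sites in wt alone and 8 in dC alone. At dC-only sites the order turned, with 30.2% (29.0-31.3%) in wt and 36.0% (34.8-37.1%) in dC cells. Both Brg1 lists reach far weaker peaks than the fetal liver lists, and at a −log10 q of at least 20 Brg1 covered 31.3% and 15.0% of the sites called with both forms and 18.98% and 0.207% of the wt-only sites. With EBF1 lists of equal length the wt-only shares were 58.7% and 13.8%.

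EBF1 itself kept many of its sites without the C-terminal domain. The peaks called with both forms were highest nearest Mib1 (89.6), Srd5a2 (86.5), Pet117 (85.4), Sh3gl3 (75.5), Megf6 (72.9), Spata48 (71.7), Cux1 (71.5), Myl10 (67.1), Actb (64.3) and Slc25a26 (63.3). Those called with wt alone were highest nearest Panx1 (45.6; chromosome 9, 15029679 to 15030473), 1190005I06Rik (44.4), Sds (40.5), Dio2 (38.4), Mapk10 (33.7), Ms4a14, Cenpm (31.9), LOC108167340, C2cd2l and Rorb. All 10 overlapped an A-MuLV Brg1 wt peak, and none a Brg1 dC peak. Within 10 kb, 3 B-lineage genes, Ikzf3 (26.4), Cd72 (13.4) and Cd79b (9.28), had a wt-only EBF1 peak (random median 1, percentile 89.7), and within 50 kb 7 had one. Peaks called with dC alone were highest nearest Odf1 (35.9), Tmem26 (29.9) and Mxi1 (27.9), and lay near 11 B-lineage genes, led by Blnk (13.4), Fcrla (9.58), Cd79b (9.31) and Pax5 (9.31; random median 6, percentile 97.6). Within 50 kb 19 had one. Myeloid genes had 6 of 14 within 10 kb, led by Itgam (11.0; percentile 98.14), and ubiquitously expressed genes 6 of 14, led by B2m (14.8; percentile 96.68), against 11 and 10 within 50 kb.

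The EBF1 wt list held 6155 peaks and the dC list 11147. Of the wt peaks 76.7% (75.6-77.7%) were called with dC, and of the dC peaks 42.1% (41.2-43.0%) were called with wt. Among 4 bins of wt fold the share called with dC rose from 63.7% through 71.1% and 80.3% to 90.9%. The highest of these bins still held 144 wt-only sites, where A-MuLV Brg1 was called at 89.6% with wt and 4.17% with dC. At these sites the fetal liver shares were 36.1% with wt, 47.2% with F-GATA3, 14.6% with dPLD and 9.72% with dC.

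Within Ikzf3, A-MuLV Brg1 and EBF1 peaks were called with wt and not with dC, though mostly at different positions. Its interval was counted after the values near it had been seen. In A-MuLV cells the gene (chromosome 11, 98464610 to 98546031) held 11 Brg1 peaks with EBF1 wt and 0 with dC. It held 2 EBF1 peaks with wt, at 98537423 to 98537915 (fold 26.4) and 98542559 to 98542908 (8.62), and 0 with dC. The first EBF1 peak overlapped 1 of the 11 Brg1 peaks (98537503 to 98537950), and the second overlapped none of them. Outside the gene but within 10 kb of it, dC cells had 3 Brg1 peaks, with folds up to 8.98, and an EBF1 peak (11.5) at a site shared with wt. The fetal liver lists had 7 Brg1 peaks in the gene with wt, 6 with dPLD, 5 with dC, 5 with F-GATA3 and 0 with the empty vector. No fetal liver list had a Brg1 peak at the first EBF1 peak. At the second, only wt had one (98542485 to 98543489). Pax5, counted in the same way, had 11 and 10 Brg1 peaks in A-MuLV wt and dC cells.

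**Figure D3:**
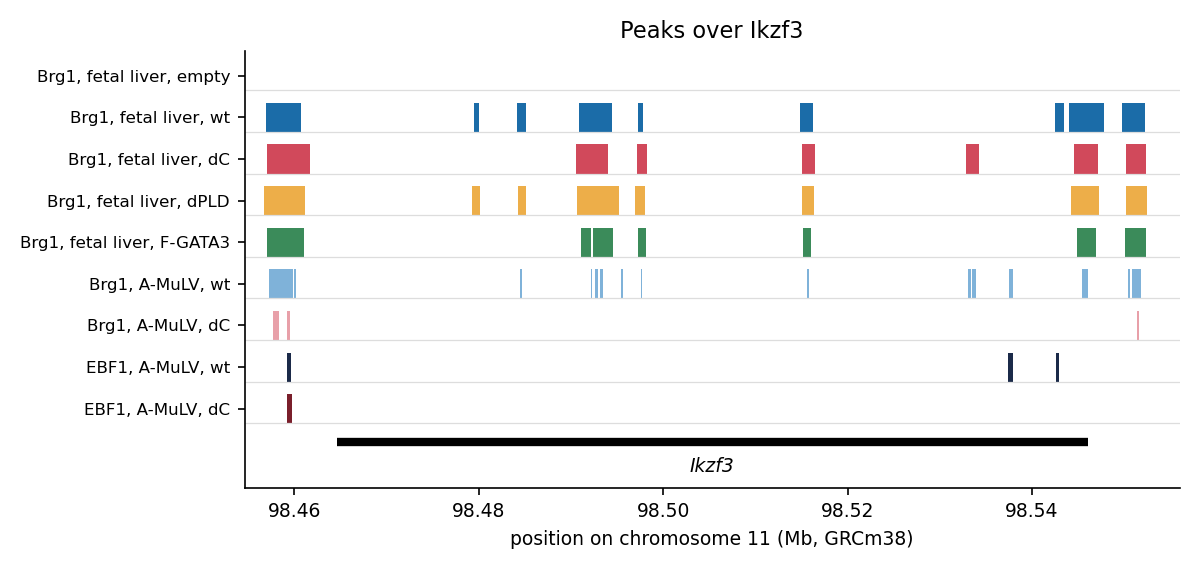
Peaks of the 9 lists around Ikzf3, with position on chromosome 11 (Mb, GRCm38) on the horizontal axis and 1 line of intervals per list. Within the gene the A-MuLV Brg1 list has 11 peaks with EBF1 wt and 0 with dC, and the EBF1 list 2 and 0.

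The immunoglobulin kappa locus, Igk, had the lowest ratio of dC to wt Brg1 peaks among the windows compared, in both kinds of cell. It was chosen after its values were seen, because the peak that the naming rule gave to Rpia lay in it. In A-MuLV cells Igk (chromosome 6, 67555636 to 70726754) held 195 Brg1 peaks with EBF1 wt and 17 with dC, and 62 EBF1 peaks with wt and 15 with dC. In fetal liver it held 141 Brg1 peaks with wt, 108 with F-GATA3, 69 with dPLD, 28 with dC and 2 with the empty vector. Of its 139 gained peaks, 26 were called with all 3 versions. The fetal liver dC to wt ratio was 0.199, below each of the 489 other windows of this length that had at least 20 wt peaks (median 1.03, lowest 0.429). The dPLD ratio was 0.489, with 1 window lower, and the F-GATA3 ratio 0.766, with 88 lower. For the empty vector the ratio was 0.014, with 0 windows lower (median 0.595). In A-MuLV cells the Brg1 ratio was 0.087 and the EBF1 ratio 0.242, each below all of the other 397 and 69 windows. The immunoglobulin heavy chain locus, Igh, showed no such drop (ratios of 1.16 in fetal liver and 1.08 in A-MuLV cells for Brg1 dC). Neither the copy number nor the rearrangement of the locus was measured here. In fetal liver the labels place wt and F-GATA3 cells at the pro-B stage, dC and dPLD cells partly blocked before it, and empty-vector cells before it. Stage and EBF1 version therefore cannot be separated there.

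**Figure D4:**
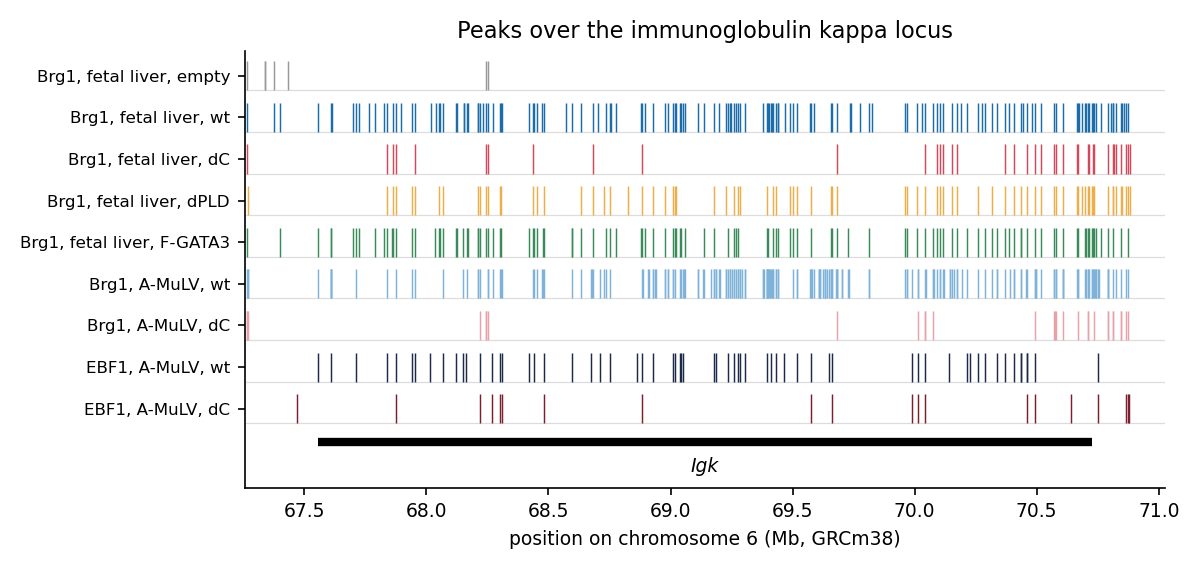
Peak midpoints across Igk, with position on chromosome 6 (Mb, GRCm38) on the horizontal axis and 1 line of marks per peak list, each mark standing for 1 peak and not drawn to its width. The A-MuLV Brg1 list has 195 peaks with EBF1 wt and 17 with dC, and the fetal liver lists have 141 (wt), 108 (F-GATA3), 69 (dPLD), 28 (dC) and 2 (empty vector).

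The genes behind the constructs and the target were looked at in every list. Gata3 held 0 peaks in all 9 lists. Smarca4 held 4 Brg1 peaks with wt (highest fold 17.3), 5 with dC, 4 with dPLD, 5 with F-GATA3 and 1 with the empty vector in fetal liver, and 11 and 6 in A-MuLV wt and dC cells. Ebf1 held 12, 12, 12 and 10 peaks with wt, dC, dPLD and F-GATA3 in fetal liver, and 21 and 15 in A-MuLV cells. Reads from the transduced Ebf1 sequence could not be told from those of the gene, since exons were not used here.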

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

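Of the tests in this part, those of a poorer Brg1 dC library and of lower enrichment of the empty-vector library were chosen only after the result was seen.

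Brg1 peak numbers with the lists as deposited moved in opposite directions in the 2 kinds of cell. The number with wt minus that with dC was −947 in fetal liver and 73 in A-MuLV cells. The A-MuLV numbers were 16251 (wt) and 14372 (dC) at a −log10 q of at least 5 and 1725 and 1088 at 20, so the size of that difference depended on the threshold. The difference was not tested, since each group had 1 library and peak numbers follow depth and threshold.

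Peaks on the unplaced scaffold JH584304.1, outside the chromosomes used, numbered 54 in the A-MuLV Brg1 wt list and 44 in the dC list. The fetal liver lists had 1 or 2 there. No biological explanation was tested.

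Brg1 was called less often with dC than with wt at EBF1 sites of A-MuLV cells, both where EBF1 dC had no peak and where both forms had one. A poorer Brg1 dC library would lower the shares everywhere. Yet away from EBF1, wt Brg1 peaks weighted to the same folds were called with dC at 73.73%, against 12.59% at wt-only EBF1 sites. This argues against a poorer library as the whole cause at the wt-only sites. Where both forms were called the share was 72.0%, not weighted by fold. The wt Brg1 peaks there had a median fold of 7.43, against 6.49 at wt-only sites. No comparison at matched folds was made where both forms were called, so a poorer library is not argued against there. Sites called with both forms have an EBF1 dC peak by definition, so sites missed by EBF1 dC do not enter the gap there. Binning by EBF1 dC fold therefore does not test missed sites and describes the gap only. Over the 2404 sites called with both forms in the highest of 4 bins, Brg1 was called more often with wt. The gap was 7.11 points (84.9% against 77.79%). In the lower 3 bins the gap was wider, with 63.4% against 25.0%, 67.1% against 34.8% and 72.7% against 49.9%, from the lowest fold up. In bins of EBF1 wt fold the gap widened instead, from 61.9% against 50.8% in the lowest to 91.8% against 70.0% in the highest. The trend thus depended on which fold set the bins. A gap that narrows as EBF1 dC fold rises is what lower occupancy by EBF1 dC could give. That occupancy, a role of the C-terminal domain in bringing in Brg1 and differences between the lines all stay open. So does a poorer Brg1 dC library where both forms were called.

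Most wt Brg1 peaks were absent from the empty-vector list, Pax5 and Ikzf3 holding none there. With lower enrichment of that library as the whole cause, nearly all of the strongest wt peaks would still be called. Of the 2936 wt peaks in the highest of 10 bins of fold, 56.74% (54.93-58.55%) were called with the empty vector, and 6840 empty-vector peaks, with folds up to 21.0, were absent from wt. This argues against it as the whole cause and is consistent with a change of Brg1 sites between the cells. A direct effect of EBF1 and the later stage of the wt cells cannot be separated in this design.

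The X chromosome held 0.678% of the empty-vector peaks (0.563-0.811%) and 1.61% of the wt peaks (1.47-1.76%). If X peaks were missed only because their wt folds were low, X and autosomal wt peaks of the same fold would be called alike. Of 472 wt peaks on X, 15.89% were called with the empty vector, against 33.38% of autosomal peaks at the same folds. This gap of 17.49 points argues against low wt folds as the whole cause. Matching was on wt fold alone. X peaks that were weaker in the empty-vector library itself could still have fallen under its threshold. The shares were 66.5% and 73.6% with F-GATA3, 78.2% and 81.2% with dPLD and 81.8% and 81.6% with dC, so the gap was not confined to the empty vector. A different mix of male and female embryos between the libraries might give such a gap, and it stays open, as untested.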

How the results depend on the processing

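The −log10 q minimum of 20 and the look at Igk were chosen only after the result was seen, while all other choices here were made before the data were examined. Some orders turned. With the lists as deposited F-GATA3 kept fewer of the gained peaks than dC and dPLD, and with equal numbers, or among gained peaks of higher fold, it kept the most. dC stood below dPLD, and above it at a −log10 q of at least 20 (78.8% against 77.6%). At wt-only EBF1 sites F-GATA3 stood just above wt, and at a −log10 q of at least 20 just below it (33.82% against 33.92%). At EBF1 sites called with both forms, wt stayed above F-GATA3, F-GATA3 and dPLD above dC, and dC above the empty vector in fetal liver under all 5 alternative thresholds, lengths and overlaps. Of these, the −log10 q minimum of 5 removed no fetal liver or EBF1 peak and could not change this order. F-GATA3 stood below dPLD only at a −log10 q of at least 20. No paired analysis was possible because each group has 1 library.

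With equal numbers of peaks, gained peaks numbered 9434, and 68.4% (dC), 75.6% (dPLD) and 75.9% (F-GATA3) of them were kept. EBF1 sites called with both forms had Brg1 at 22.7% (empty vector), 68.3% (wt), 55.9% (dC), 63.7% (dPLD) and 65.5% (F-GATA3) in fetal liver and at 79.6% (wt) and 66.3% (dC) in A-MuLV cells. EBF1 wt peaks called with dC came to 63.3%, and dC peaks called with wt to 62.8%. Of wt-only EBF1 sites with Brg1 in 1 of wt and dC, 90.3% (fetal liver) and 97.4% (A-MuLV) had it with wt. The EBF1 dC list lost peaks here and the wt list did not, which by construction lowers the share of wt peaks called with dC; the cause of the other changes was not tested. The A-MuLV Brg1 shares at wt-only sites were 58.7% (wt) and 13.8% (dC), and they were 45.6% and 4.04% at a −log10 q of at least 5 and 18.98% and 0.207% at 20.

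At a −log10 q of at least 5, which removed only A-MuLV Brg1 peaks, sites called with both forms had Brg1 at 68.4% (wt) and 47.8% (dC), and 59.5% of wt Brg1 peaks were called with dC and 68.5% the other way. At 20, dC kept 78.8% and F-GATA3 66.4% of the gained peaks. Brg1 covered 7.10% (empty vector), 73.0% (wt), 58.5% (dC), 64.8% (dPLD) and 64.2% (F-GATA3) of the sites called with both forms in fetal liver, and 31.3% (wt) and 15.0% (dC) in A-MuLV cells. The A-MuLV Brg1 overlaps were 30.8% of wt and 49.4% of dC peaks, with 1725 and 1088 peaks left, and the EBF1 overlaps 73.2% and 45.7%.

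With an overlap of 50% of the shorter peak, sites called with both forms had Brg1 at 19.1% (empty vector), 74.995% (A-MuLV wt) and 57.0% (A-MuLV dC), and the A-MuLV Brg1 overlaps were 57.2% of wt and 60.1% of dC peaks. With summits within 200 bp, 66.0% (dC), 66.4% (dPLD) and 62.1% (F-GATA3) of the gained peaks were kept. Sites called with both forms had Brg1 at 9.96% (empty vector), 57.5% (wt), 42.4% (dC), 49.2% (dPLD), 53.8% (F-GATA3), 66.7% (A-MuLV wt) and 49.9% (A-MuLV dC). The A-MuLV Brg1 overlaps were 46.9% and 47.2%, and 98.4% (fetal liver) and 96.8% (A-MuLV) of the wt-only sites with Brg1 in 1 of wt and dC had it with wt.

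Among gained peaks above the median fold of the shared peaks, 89.3% (dC), 95.4% (dPLD) and 95.7% (F-GATA3) were kept. The cause of the changes with threshold, overlap and fold was not tested. With gene bodies extended by 50 kb, 50 of the counts of list members stayed within 1.5 times and 31 did not. Over Igk, equal numbers left 97 (wt), 75 (F-GATA3), 49 (dPLD) and 16 (dC) fetal liver peaks, and a −log10 q of at least 20 left 99, 67, 47 and 17. The A-MuLV Brg1 counts over Igk, 195 (wt) and 17 (dC), are given for the lists as deposited only. Those lists reach down to −log10 q values of 1.37 and 1.33, so the counts include weak peaks. Motifs in 2 variants and windows of 2 kb around transcription starts were not run, for want of sequence and strand here. Unknown depth limits every absence of a peak.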

Other observations

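Genes of several other lineages lay near Brg1 peaks found with the empty vector and absent with wt EBF1. Such peaks were within 10 kb of 8 of 14 myeloid genes, led by Fcgr3 (fold 10.0), which encodes an Fc receptor, Itgam (8.42), Cebpa (8.25) and Cebpb (6.62), against a random median of 2 (percentile 100). They were near 6 of 12 innate lymphoid and NK genes, led by Rora (12.9) and Zbtb16 (7.93; percentile 99.63), near 7 of 16 T-lineage genes, led by Lck (8.94) and Ptcra (7.43; percentile 97.88), and near 6 of 12 progenitor genes, led by Flt3 (13.1), Meis1 (8.94) and Hoxa9 (7.66; percentile 96.76). Only 1 of 26 B-lineage genes, Bach2 (10.5), had such a peak (percentile 1.28), although 8 had one within 50 kb (percentile 27.24). Erythroid and megakaryocyte genes had 1 of 10, Itga2b (6.45; percentile 55.44). Of 11 stromal genes 1, Pdgfrb (12.8), had one within 10 kb (percentile 21.64). The highest of these peaks were nearest Gpr33 (21.0), Cspg4b (20.7) and Agtr1b (19.02), genes chosen after their values were seen.

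Progenitor genes had more peaks in A-MuLV dC cells than in wt cells. Within 10 kb of their 12 members lay 41 Brg1 peaks with dC and 17 with wt, and 17 EBF1 peaks with dC and 4 with wt. The EBF1 dC list was the longer (11147 against 6155 peaks), and most other gene lists also had more EBF1 peaks with dC. Myeloid genes had 12 against 3 and BAF and PBAF genes 28 against 13, while erythroid and megakaryocyte genes had 4 against 5. The number of members with a Brg1 peak was 5 with dC and 4 with wt, so most of the gap came from several peaks at the same genes. Brg1 peaks seen only with dC lay near Erg (14.3), Runx1 (7.31), Flt3 (5.87) and Tal1 (4.62), which encode factors and a receptor of blood progenitors (percentile 64.48).

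Some T-lineage genes carried both EBF1 peaks called with wt alone and EBF1 peaks called with dC alone. Peaks called with wt alone lay near Tcf7 (9.14), Zap70 (8.36), Cd247 (6.53) and Il2ra (6.09), 4 of 16 members against a random median of 1 (percentile 99.42). Peaks called with dC alone lay near the same genes, at folds of 8.21, 7.39, 10.7 and 8.07, and near Notch1 (16.7) and Runx3, 6 members against a random median of 4 (percentile 83.05). In all, 16 EBF1 wt and 20 EBF1 dC peaks lay near the list. No innate lymphoid and NK gene lay near a Brg1 peak seen only with wt in A-MuLV cells (random median 3, percentile 1.0), while 4 did within 50 kb.

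The place of the remaining Brg1 peaks in Igk was looked at after the values were seen. Of the 28 fetal liver dC peaks, 10 lay in the last of 10 equal segments of the locus and 6 in the one before it, against 18 and 14 of the 141 wt peaks. Of the 17 A-MuLV dC peaks 8 lay in the last segment, 0 in the ninth, 4 in the eighth, 1 in the seventh and 4 in the third, against 26, 21, 14, 32 and 15 of the 195 wt peaks. The Igh locus held 111 fetal liver Brg1 peaks with wt, 129 with dC, 124 with dPLD, 93 with F-GATA3 and 53 with the empty vector.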
